A study of Mus musculus with 7 samples.

How the data were processed

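Total RNA from liver of C57BL/6 mice had been extracted with the Direct-zol RNA MiniPrep kit and made into Illumina libraries, per the labels' protocols. Per the submitters' processing notes the tools were cutadapt 1.11, TopHat2 2.1.1 and Cufflinks 2.2.1, and the build was mm9. Their settings, the gene annotation, the read length and whether strand was used were not given in the sources used here. The deposited values were FPKM per gene, as Cufflinks writes them, in 1 table of 37468 rows per library with a lower and an upper bound and a status for each row, per the file headers. No further normalization was applied to the deposited FPKM values. Gene symbols, gene IDs and coordinates were taken from the tables as given. Positions are on mm9 and counted from 1. A GRCm38 reference was not used for coordinates, since Myod1 starts at 53631844 in the tables and at 46376474 in that reference.

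Read counts and library sizes were unknown. The deposited bounds gave only a relative depth: over 5579 genes, with each bound taken as 2 SD of a counting error, it lay between 0.949 and 1.09 of the geometric mean of the 7 libraries. Between 8.11% and 9.41% of rows per library had a value outside their own bounds, so the bounds were not used as errors of the values. The FPKM sums lay between 1.26e+06 and 1.97e+06, and genes spanning less than 300 bp took 40.5% to 57.9% of them. Fragment lengths were not given in the sources used here, so how far the values of such short genes can be trusted was not tested. The mitochondrial tRNA mt-Ts1 alone took 26.3% to 33.4% of the sum in the WT and SunTag libraries and 5.80% to 8.32% in the 3 libraries of the Myod1 experiment. Rows with a failed status, 1 to 7 per library, were listed at 0. Such rows were left out before testing, and every Myod1 value had the status OK, so the zeros reported are not rows that failed. Genes listed at 0 are given as their value in each library and without a fold.

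Rows whose status was not OK in any library were left out, 343 rows, and rows that shared a symbol were summed, for 244 symbols. A gene was tested if it reached an FPKM of 1 in at least 1 library, and Myod1 was kept whatever its value, which gave 15744 genes, 1229 of them spanning less than 300 bp. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 7 libraries and an empirical Bayes variance that follows the mean (3 residual and 1.93 prior degrees of freedom). All tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. A log2 difference on this scale understates the change of low genes. The median gene shifted by 0.25 between Myod1_active and Myod1_control, by -0.14 between Myod1_control and SunTag and by 0.01 between SunTag and WT, so log2 differences are given relative to the median gene of the comparison unless said otherwise. The SE and p-values of limma and the counts of genes called higher or lower used the differences before that shift was taken off. So did the shares of genes whose groups did not overlap. The libraries are numbered as replicates, and nothing in the labels says that they came from separate animals, so p-values measure only the spread between these libraries, which can be technical. Any 2 tables shared at most 1 identical value above 0 in 37468 rows, so no library was counted as a copy of another. Replicate numbers were not treated as pairs.

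The 3 comparisons were SunTag against WT, Myod1_active against Myod1_control, and, as background, Myod1_control against SunTag. The design, the gene lists, the rule for named genes and the alternatives were set before the data were examined, except where said. The 33 lists held 780 genes, 770 with a row, and covered hepatocyte functions, stress responses, sex bias, other cell types of liver and blood, and muscle. The 32 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01 and, beside it, with an estimated correlation and with fry. camera compares a list with all other genes, while fry asks whether its members move one way on balance. fry used differences from which the shift of the median gene was not taken off. Adjustment was over the lists of a comparison. Genes were named by rule: among genes past the threshold whose groups did not overlap, the 10 with the largest log2 difference in each direction, filled up to 5 by the smallest p-values; up to 4 members of each list; and always Myod1, Myog, Myf5, Myf6, Des, Ckm, Acta1, Alb and the neighbours of Myod1 within 500 kb. Predicted genes, clones and small RNAs were counted and not named, and fewer were named than the rule allows. Lists of heart muscle and fast skeletal muscle genes were added after the heart genes were seen.

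The same code was tested on simulated libraries with the means and moderated spreads of the real genes and 200 changed genes, drawn among those with a mean log2 value of at least 1, in each of 10 draws, on 14908 to 14991 genes. For SunTag against WT it recovered 27.6% of genes changed by 1 on the log2 scale, 84.8% of those changed by 2, 88.0% by 3 and 91.8% by 4, with 12 false calls per draw. For Myod1_active against Myod1_control it recovered 5.60%, 68.4%, 81.8% and 87.2%, with 8.70 false calls, and for Myod1_control against SunTag 21.4%, 83.8%, 90.2% and 91.6%, with 10.2 false calls. A list shifted by 0.5 was called in 10 of 10 draws of each comparison with the preset correlation and in 0 of 10 with an estimated correlation, and 1 of 309 lists without a shift was called. Genes were simulated as independent, so this does not measure how often camera calls correlated lists by mistake.

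Alternatives were a pseudocount of 0.1, no filter beyond a value above 0, a filter on the mean FPKM, median-ratio scaling, quantile normalization, no variance trend, only the groups compared, the replicate number as a block, rows kept whatever their status, symbols with more than 1 row left out, an added 2-fold threshold, an estimated correlation for lists, and leaving out each library of the groups with 2. Added after seeing the data were a minimum span of 300 bp, alone and with median-ratio scaling. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.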

Results

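RNA from C57BL/6 mouse liver was sequenced in 7 libraries that fell into 4 groups by their labels: 2 libraries of wild-type mice (WT), 2 of SunTag-dCas9 mice (SunTag), 1 labelled as Myod1 activated (Myod1_active) and 2 controls of that experiment (Myod1_control). The last 3 libraries also came from SunTag-dCas9 mice. dCas9 is a Cas9 protein that binds DNA where its guide RNA matches and does not cut it, and SunTag is a repeated peptide tag that recruits several effector proteins to one such site. How Myod1 was activated, and what the controls received, was not given in the sources used here. Expression was given as FPKM, fragments per transcript length and library size, for 37468 rows per library. Between 13204 and 14044 genes per library reached an FPKM of 1. Total read counts were unknown, and the width of the deposited intervals placed the depth of the libraries between 0.949 and 1.09 of their geometric mean. Across genes, which are not independent replicates, the log2 values of WT replicates 1 and 2 and SunTag replicate 2 correlated with Pearson's r of 0.989 to 0.990. SunTag replicate 1 stood apart from these 3 libraries, at 0.975 to 0.980, and the 3 libraries of the Myod1 experiment correlated at 0.901 to 0.937 with the other 4.

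The comparison of Myod1_active with Myod1_control asked what changed in liver when Myod1 was activated. Myod1 (ENSMUSG00000009471), a transcription factor that drives cells towards skeletal muscle, spans 53631844 to 53634462 on chromosome 7 of the mm9 build. Its FPKM was 3.52 in the Myod1_active library, with a deposited interval of 2.81 to 3.88, and it was listed at 0 in both Myod1_control, both SunTag and both WT libraries. On the log2(FPKM + 1) scale the difference from the controls was 2.18 (SE 0.181, 1 library against 2, limma adjusted p = 0.0327). That value depends on the pseudocount and is not a fold, since the controls were listed at 0. Among other settings, the call ended with a pseudocount of 0.1 (adjusted p = 0.173), with a filter on the mean FPKM (0.0883), with quantile normalization (0.0518) and in a fit of these 3 libraries alone (0.0847). The activated group held 1 library, so there was no replicate check of that arm, and the fit assumed that it varies like the other groups.

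The other muscle-determining factors were near 0. Myog, which acts after Myod1 in muscle differentiation, was listed at 0 in Myod1_active and at 0 and 0.0424 FPKM in the controls, and Myf5 and Myf6 were listed at 0 in all 3 libraries. Des, an intermediate filament protein of muscle, was at 0.208 FPKM against 0.154 and 0.384 (adjusted p = 0.914), and Ckm, the muscle creatine kinase, at 0.0194 against 0.0895 and 0.0223, below the filter of the test. Acta1, which the naming rule also covers, had no row under that symbol among the deposited values, so it was not analysed here. Of the 19 listed myogenic regulators 5 were expressed enough to test: 1 passed, Myod1 itself, and 4 did not. Adjusted over the list alone, 3 were higher, Myod1, Hes6 and Mef2a. Hes6, a transcriptional regulator that promotes differentiation, was at 142 FPKM against 67.7 ± 6.60 (SD, n = 2; adjusted p over all genes = 0.171), and Mef2a, a partner factor of Myod1, at 7.10 against 4.18 ± 0.502 (adjusted p = 0.171). The list as a whole had a median log2 difference of 0.39 relative to the median gene (camera adjusted p = 0.157, and 0.742 with an estimated correlation). With no filter on low values the median over 14 members was -0.0683 (camera adjusted p = 0.994). That value only reflects the shift of the median gene taken off in that fit, so it does not show a fall. The members added there were below an FPKM of 1 in every library. fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0340 over the 5 tested members, which include the activated target itself. Of 11 tested skeletal muscle contractile and excitation genes none passed limma's test and 9 lay below the median gene (median -0.25, camera adjusted p = 0.172, and 0.742 with an estimated correlation). That median is the size of the shift of 0.25 taken off every gene, so it does not show a fall of the list. The mean log2 value of the list was 1.04 in Myod1_active and 0.809 and 1.05 in the controls. Mylpf, a fast muscle myosin light chain, was at 4.36 FPKM against 0.144 and 1.31 (adjusted p = 0.246). It was at 4.09 and 1.77 FPKM in WT and 5.77 and 2.70 in SunTag, where Myod1 was listed at 0, so 4.36 is within their range.

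Within 500 kb of Myod1 the files held 27 further genes, of which 16 were tested and 0 passed limma's test. Without adjustment, 2 of the 16 had p under 0.05. In 12 of the 16 the activated library lay outside the range of the 2 controls, where chance gives 66.7% and all tested genes gave 78.0%. The lowest adjusted p was 0.158, for Tmem143, at 36.8 FPKM against 15.7 ± 0.571 (SD, n = 2).

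Of 15744 genes tested, 34 were higher and 6 lower in Myod1_active, and 5 of the 40 carried a name other than that of a predicted gene or a small RNA. Besides Myod1 these were Cryab, Orm2, Cpm and Derl3, with log2 differences given relative to the median gene because the median of all genes shifted by 0.25 between the groups. The SE and adjusted p belong to the differences before that shift was taken off. Those were 3.88 for Cryab, 3.72 for Orm2, 2.21 for Cpm and -3.60 for Derl3. Cryab, a small heat shock protein abundant in muscle, rose to 27.95 FPKM from 0.967 ± 0.199 (SD, n = 2; log2 difference 3.63, SE 0.276, adjusted p = 0.0182). Orm2, an acute phase plasma protein, rose to 814 FPKM from 62.1 ± 17.4 (3.47, SE 0.314, adjusted p = 0.0344), a value that is uncertain because its near-identical neighbour Orm3 can share reads with it. Cpm, a membrane carboxypeptidase, rose to 7.76 FPKM from 0.891 ± 0.0744 (1.96, SE 0.163, adjusted p = 0.0206). Derl3, which takes part in the degradation of misfolded proteins of the endoplasmic reticulum, fell to 0.935 FPKM from 22.5 ± 3.20 (-3.85, SE 0.178, adjusted p = 0.00473), and was at 1.52 to 1.87 FPKM in the SunTag and WT libraries. The WT and SunTag libraries lay between Myod1_active and the controls for Cryab, at 4.003 to 6.14 FPKM, and for Orm2, at 165 to 249, so the controls were the lowest of the 7 libraries for both, while Cpm was at 0.705 to 0.863 in the WT and SunTag libraries. Those libraries came from another experiment and, by the Xist and Y-linked values given below, from the other sex. Their levels are therefore no baseline for Myod1_active or its controls. Myod1 and Derl3 passed with any 1 library left out, but without a control library 1 library stood against 1 and all of the spread came from the WT and SunTag groups. Cryab did not pass without WT replicate 1 (adjusted p = 0.111), WT replicate 2 (0.111), Myod1_control replicate 1 (0.0885) or Myod1_control replicate 2 (0.0954). Orm2 did not pass without WT replicate 1 (0.157), WT replicate 2 (0.162), SunTag replicate 1 (0.119), SunTag replicate 2 (0.121) or Myod1_control replicate 2 (0.0856), and Cpm did not pass without WT replicate 1 (0.0724) or WT replicate 2 (0.0722). With a pseudocount of 0.1 neither Orm2 (0.0529) nor Cpm (0.0671) passed.

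**Figure D1:**
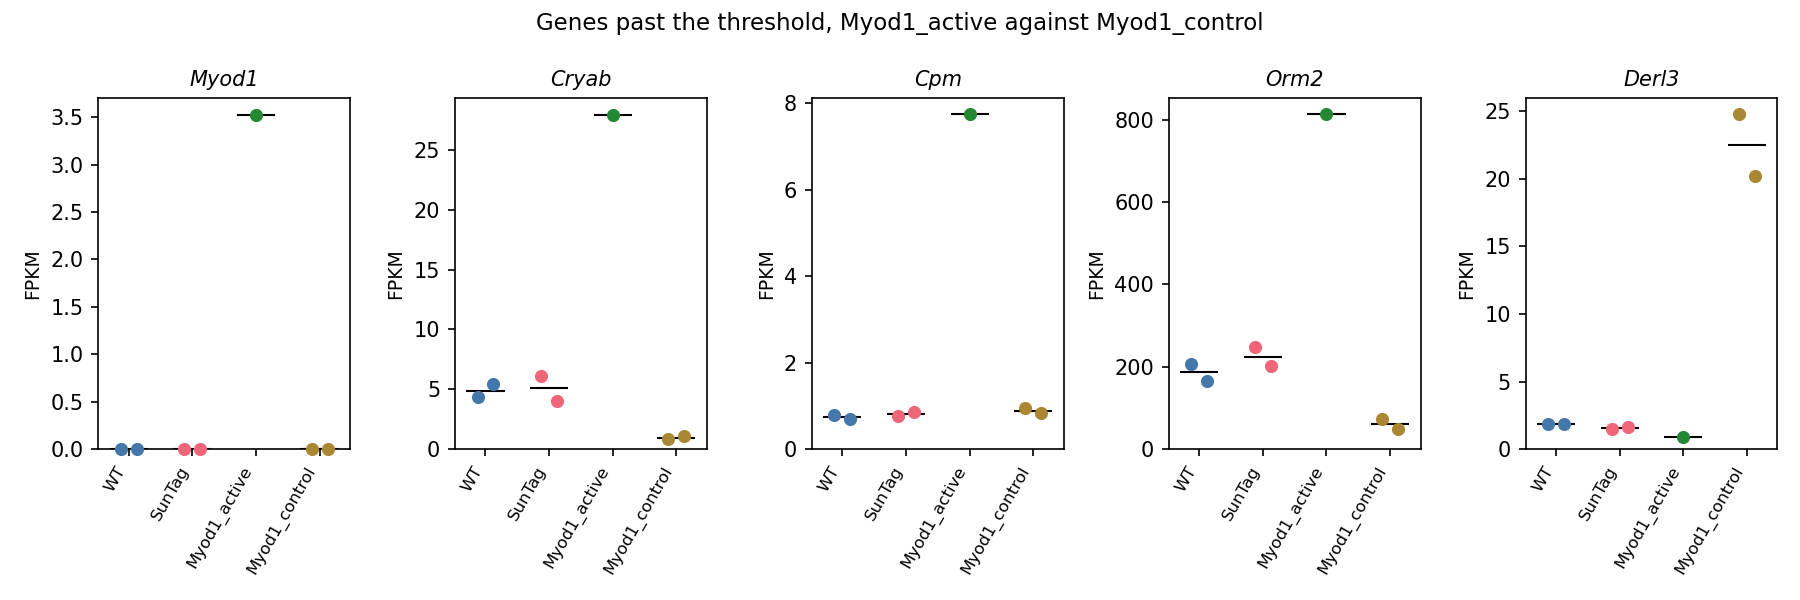
FPKM (vertical axes, linear from 0) of Myod1, Cryab, Cpm, Orm2 and Derl3 in each of the 7 libraries (points) by group, with the group mean as a line. Myod1 was at 3.52 FPKM in the Myod1_active library and listed at 0 in the other 6, and Derl3 was at 0.935 in that library against 24.8 and 20.2 in the controls.

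Of the 40 calls, 33 were genes spanning less than 300 bp. With those left out of the test, a choice made after seeing the data, 17 genes were higher and 3 lower, 7 of them shared with the 40. Median-ratio scaling on top of that left 6 higher and 3 lower, again with 7 shared. Among the genes that passed with the short genes left out and not over all genes were Elovl3, Pitx3, Orm3, Mogat2, Chi3l1, Furin and Ssbp4. With median-ratio scaling added, Elovl3 and Pitx3 still passed and the other 5 did not. Furin, a protease that activates secreted proteins, was at 495 FPKM against 99.9 ± 5.22 (SD, n = 2; adjusted p over all genes = 0.0719), Mogat2, an enzyme of triglyceride synthesis, at 10.5 against 0.682 and 0.0687 (0.0890), and Chi3l1, a secreted chitinase-like protein, at 4.14 against 0.365 and 0.126 (0.0645). Ssbp4 was at 7.57 FPKM against 1.41 ± 0.153 (0.0584) and Orm3 at 78.3 against 7.69 ± 2.83 (0.0853). Elovl3, a fatty acid elongase that is higher in male liver, was at 63.9 FPKM against 333 ± 66.0 (0.0584, and 0.0349 with median-ratio scaling of all genes), and Pitx3 at 4.36 against 35.3 ± 12.9 (0.0961). Pitx3 is uncertain, since its span (46210175 to 46222865 on chromosome 19) overlaps the end of Elovl3 (46206387 to 46210184). Il6ra, the interleukin 6 receptor, was at 3.09 FPKM against 8.66 ± 0.516 and did not pass (0.123). Leaving out 1 library, which for a control takes all of the spread from the WT and SunTag groups, brought past the threshold Pitx3 (without Myod1_control replicate 1, adjusted p = 0.0232, and without replicate 2, 0.0135), Furin (without SunTag replicate 1, 0.0333, and without SunTag replicate 2, 0.0342) and Chi3l1 (without Myod1_control replicate 1, 0.0332).

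The count of 40 and its split into 34 higher and 6 lower moved with the libraries and settings of the test. Without Myod1_control replicate 1 the test called 122 genes (58 higher and 64 lower), 35 of them among the 40, and without Myod1_control replicate 2 it called 94 (45 and 49), with 33 shared. It rose to 253 (239 higher and 14 lower) with no filter on low values and fell to 23 (13 higher and 10 lower) with a pseudocount of 0.1, and a fit of these 3 libraries alone called 0 genes with limma, where 2611 had an unadjusted p under 0.05. At an unadjusted p under 0.05 the 7-library fit gave 3067 genes, against 787 by chance, and 2032 with median-ratio scaling and 1951 with quantile normalization. The activated library lay outside the range of the 2 controls for 78.0% of genes, where chance gives 66.7%, and by at least 2-fold relative to the median gene for 446 higher and 433 lower genes. The 78.0% was counted before the shift of 0.25 was taken off, and such a shift can itself raise that share. An exact rank test of 1 library against 2 cannot give a two-sided p under 0.667.

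Several hepatocyte programs, and the markers of endothelial cells, lay lower in Myod1_active as groups. The 28 tested genes of fatty acid oxidation and PPAR alpha targets had a median log2 difference of -1.07 relative to the median gene, and 26 lay below it (camera adjusted p = 1.99e-13, and 0.694 with an estimated correlation). Their mean log2 value was 5.59 in Myod1_active, 6.13 and 6.60 in the controls and 5.19 to 5.57 in the WT and SunTag libraries, so the controls were the highest. The gap between the controls and the WT and SunTag libraries also separates experiments and sexes, so it does not mark the controls as unusual. None of the 28 passed limma's test alone, over all genes or adjusted over the list alone. Examples were the fatty acid binding protein Fabp1 at 1300 FPKM against 2899 ± 272 (SD, n = 2) and the peroxisomal thiolase Acaa1b at 441 against 1023 ± 244. Male-biased liver genes had a median of -1.13, and 18 of 19 lay below the median gene (camera adjusted p = 2.14e-11, and 0.694 with an estimated correlation). None passed over all genes, and 1 was lower adjusted over the list alone. The major urinary proteins Mup3, at 1713 FPKM against 3804 ± 822, Mup7, at 1385 against 5072 ± 2639, and Mup20, at 1139 against 2804 ± 1187, belong to a family of near-identical copies and are uncertain one by one. The 19 endothelial cell markers all lay below the median gene, with a median of -0.74 (camera adjusted p = 3.31e-11, and 0.694 with an estimated correlation), and 0 passed limma's test over all genes or over the list alone, where Clec4g, Stab1 and Eng, genes of the liver's sinusoids and vessels, were at 8.90 against 13.1 ± 0.540, 4.75 against 7.33 ± 1.07 and 11.3 against 14.9 ± 0.807 FPKM. Bile acid synthesis and transport had a median of -0.72 with 14 of 16 members lower (camera adjusted p = 5.77e-07, and 0.694 with an estimated correlation). Cyp27a1, an enzyme of the alternative bile acid pathway, was at 219 FPKM against 357 ± 19.3, and the bile salt pump Abcb11 at 168 against 221 ± 11.5. Estimated correlations were 0.352 for the PPAR alpha, 0.536 for the male-biased, 0.112 for the endothelial and 0.148 for the bile acid list, above the preset of 0.01. The preset p-values thus take related genes of 1 activated library as nearly independent, and overstate the evidence. fry gave an adjusted p of 0.311 for the PPAR alpha and the male-biased list.

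Relative to the median gene, 5 more lists lay lower by a smaller amount, and in none of them did a gene pass over all genes or over the list alone. The medians were -0.47 for the unfolded protein response (18 of 22 below the median gene, camera adjusted p = 0.00110), -0.42 for pericentral hepatocyte genes (14 of 21, 0.00292), -0.35 for xenobiotic metabolism (19 of 29, 0.00313), -0.35 for female-biased liver genes (15 of 22, 0.0342) and -0.23 for hepatocyte secreted proteins (22 of 29, 0.0194). With an estimated correlation these adjusted p-values were 0.742, and 0.853 for the pericentral list. Cyp2e1, a pericentral cytochrome P450, was at 1203 FPKM against 2971 ± 106 (SD, n = 2). The chaperone Hspa5 was at 618 FPKM against 531 and 1111, so it lay between the controls, and the chaperone Hsp90b1 at 365 against 424 and 677. Albumin, Alb, was at 28500 against 33008 ± 3426, and the hepatocyte transcription factor Hnf4a at 120 against 166 ± 22.1. Above the median gene lay ribosomal proteins, at 0.31 with all 35 tested genes higher (camera adjusted p = 0.0342, and 0.927 with an estimated correlation), and the mitochondrial respiratory chain, at 0.24 with 27 of 29 higher (0.00292, and 0.742 with an estimated correlation). Rpl18 was at 499 FPKM against 333 ± 32.8 and Atp5b, a subunit of ATP synthase, at 1931 against 1440 ± 29.3, and no member of either list passed over all genes or over the list alone.

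In all, 11 of 32 lists passed camera with its preset correlation, 2 higher and 9 lower, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. In the simulation the estimated correlation called 0 of 10 lists shifted by 0.5, so not passing it does not decide whether a list changed. fry gave 1 list, the myogenic regulators. Since it does not take off the shift of 0.25, it favours lists that rise here over lists that fall. The lowest camera adjusted p among the other 21 was 0.0512, for stellate cell and matrix genes. Quantile normalization left 7 of the 11, and ended the calls for the secreted proteins, whose median turned to 0.19 (adjusted p = 0.125), the pericentral genes (0.0699), xenobiotic metabolism (0.0917) and the female-biased genes (0.573). Median-ratio scaling ended those for the female-biased genes (0.565) and the respiratory chain (0.0758), as it did with the short genes left out (0.417 and 0.0907). With no filter the secreted proteins (0.122) and female-biased genes (0.224) did not pass, and the latter also not with a pseudocount of 0.1 (0.166) or in a fit of these 3 libraries alone (0.367). Ribosomal proteins did not pass without WT replicate 1 (0.0829), WT replicate 2 (0.0842), Myod1_control replicate 1 (0.120) or Myod1_control replicate 2 (0.323), secreted proteins without Myod1_control replicate 1 (0.182), and xenobiotic metabolism (0.0566) and female-biased genes (0.128) without Myod1_control replicate 2. Fatty acid oxidation, male-biased, endothelial, bile acid, unfolded protein response, pericentral and respiratory chain lists passed with any 1 library left out, where the fits without a control set 1 library against 1 and took their spread from WT and SunTag alone. Median, mean and test direction had one sign in each of the 11, and differed in sign in 6 of the others.

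The comparison of SunTag with WT asked how the liver transcriptome of mice carrying the knock-in differed from that of wild-type mice. Of the 12 genes that were lower in SunTag, 5 were heart muscle genes and the rest were predicted genes or small RNAs that span less than 300 bp. Myl2, the regulatory light chain of ventricular myosin, was at 15.0 and 14.6 FPKM in the WT libraries and listed at 0 in both SunTag libraries (adjusted p = 0.00168). Mb, myoglobin, was at 7.85 and 8.72 FPKM and listed at 0 in both SunTag libraries (0.00457), Myl3 at 5.20 and 6.76 and at 0 in both (0.0157), and Myh6, the alpha cardiac myosin heavy chain, at 3.81 and 4.31 and at 0 in both (0.0165). Tnnt2, cardiac troponin T, fell from 8.20 ± 0.841 to 0.254 ± 0.0434 FPKM (SD, n = 2 each; log2 difference -2.89 relative to the median gene, SE 0.145, adjusted p = 0.00716). The first 4 of these were also listed at 0 in the 3 libraries of the Myod1 experiment, as was Tnnt2. Further heart genes, chosen after their values were seen, differed the same way without passing: Tnni3, cardiac troponin I, was at 8.05 ± 1.09 FPKM in WT against 1.12 ± 0.667 in SunTag (adjusted p = 0.269), Actc1, cardiac actin, at 2.63 ± 0.635 against 0.109 ± 0.127 (0.385), and Pln, phospholamban, at 1.90 ± 0.0362 against 0.294 ± 0.0802 (0.269). Myl3 did not pass without SunTag replicate 1 (adjusted p = 0.0561), SunTag replicate 2 (0.0542), Myod1_control replicate 1 (0.0771) or Myod1_control replicate 2 (0.0747), nor in a fit of these 4 libraries alone (0.0746), and Myh6 did not pass with a pseudocount of 0.1 (0.0932).

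**Figure D2:**
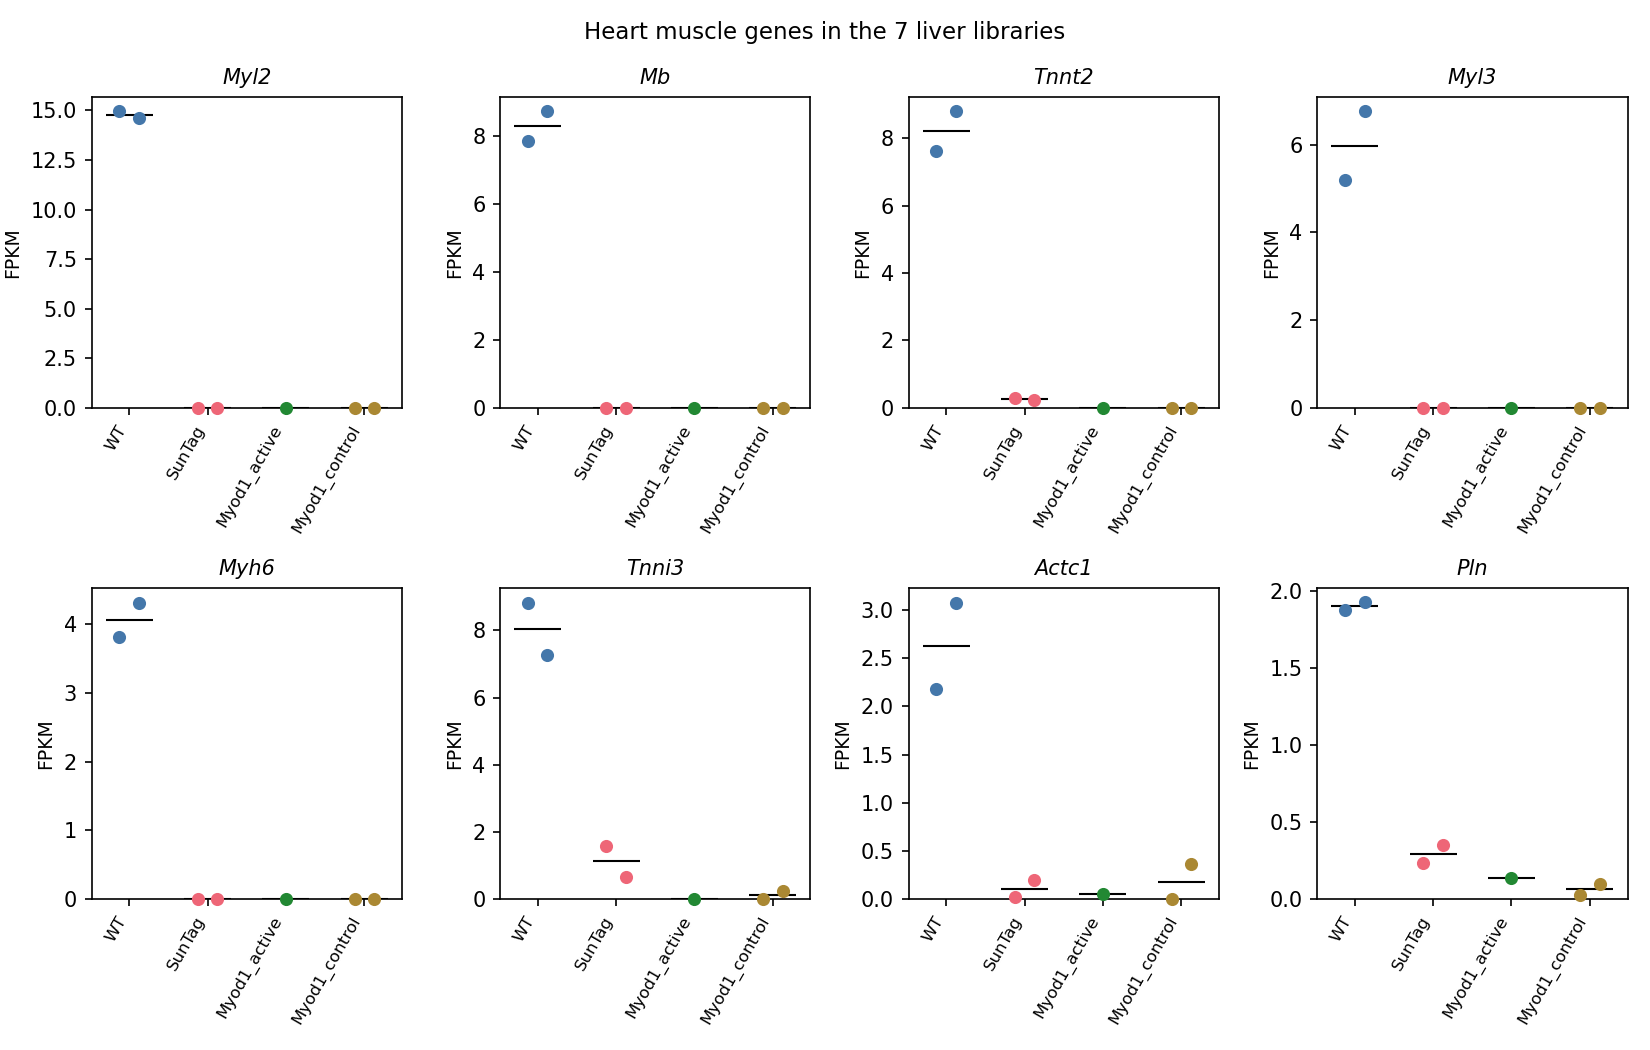
FPKM (vertical axes, linear from 0) of 8 heart muscle genes in each of the 7 libraries (points) by group, with the group mean as a line. Myl2 was at 15.0 and 14.6 FPKM in the WT libraries and listed at 0 in the other 5, while Tnni3, Actc1 and Pln did not pass the test between SunTag and WT.

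Of 15744 genes tested, 8 were higher and 12 lower in SunTag, and 307 had an unadjusted p under 0.05 against 787 by chance. The groups did not overlap for 25.8% of genes, where chance gives 33.3%. Of the 20 calls, 15 spanned less than 300 bp and 14 were predicted genes or small RNAs. With the short genes left out, a choice made after seeing the data, 0 genes were higher and 5 lower with limma, the 5 heart genes that passed, and 279 had an unadjusted p under 0.05. The 1 higher gene with a name of its own was Ighj1, a joining segment of the immunoglobulin heavy chain that spans 53 bp, listed at 0 in both WT libraries and at 144 and 161 FPKM in the SunTag libraries (adjusted p = 0.000531). The next genes by p-value did not pass: Cklf was at 1.202 ± 0.00228 FPKM in WT against 3.08 ± 0.0248 in SunTag, Fam89a at 5.54 ± 0.339 against 9.18 ± 0.594, Ms4a4c at 0.416 ± 0.0939 against 1.65 ± 0.454 and Tprn at 2.42 ± 0.694 against 5.13 ± 0.167 (SD, n = 2 each; adjusted p = 1 for each of them). Albumin, Alb, was at 51493 ± 3676 FPKM in WT against 47374 ± 1269 in SunTag and Hnf4a at 157 ± 4.56 against 142 ± 5.25. Myod1 was listed at 0 in all 4 libraries. The count of 20 grew, and its split moved with the library left out, to 61 without WT replicate 1 (8 higher and 53 lower), 78 without WT replicate 2 (9 and 69), 75 without SunTag replicate 1 (59 and 16) and 76 without SunTag replicate 2 (63 and 13), with 17 or 18 of the 20 among them each time. An exact permutation test of 2 libraries against 2 cannot give a two-sided p under 0.333.

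Red cell genes lay higher in SunTag. The erythroid list of 9 tested genes had a median log2 difference of 1.01 relative to the median gene, with 7 members above it (camera adjusted p = 1.87e-05, and 0.821 with an estimated correlation). No member passed over all genes, and 5 were higher adjusted over the list alone. The alpha globin Hba-a1 was at 758 ± 17.3 FPKM in WT and 1580 ± 491 in SunTag, and the beta globin Hbb-b1 at 617 ± 29.3 and 1456 ± 560 (SD, n = 2 each), values that are uncertain because each has a near-identical copy. This was the only list of the 13 called that passed with any 1 library left out.

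Of 32 lists, 13 passed camera with its preset correlation, 8 higher and 5 lower, while 0 passed with an estimated correlation, where 1 had an unadjusted p under 0.05, and 0 passed fry, whose lowest adjusted p was 0.171. With an estimated correlation the adjusted p was 0.821 for each of the 13. That setting called 0 of 10 shifted lists in the simulation, so it cannot decide against them. The estimated correlations ran from 0.106 for the erythroid to 0.701 for the cell cycle list, above the preset of 0.01, so the preset p-values overstate the evidence. No gene of the other 7 higher lists passed, over all genes or adjusted over the list alone. Their medians relative to the median gene were 0.41 for stellate cell and matrix genes (17 of 20 higher, camera adjusted p = 1.57e-06), 0.29 for macrophage and Kupffer cell markers (24 of 24, 0.00194), 0.27 for lymphocyte and NK cell markers (16 of 17, 0.00410), 0.23 for cell cycle genes (22 of 26, 0.00712), 0.22 for immediate early genes (12 of 16, 0.00553), 0.21 for the mitochondrial respiratory chain (27 of 29, 5.35e-06) and 0.12 for the interferon response (25 of 37, 0.0429). Lower lay female-biased liver genes at -0.43 (17 of 22 lower, 0.0429), skeletal muscle contractile and excitation genes at -0.26 (8 of 11, 0.00222), bile acid synthesis and transport at -0.24 (12 of 16, 0.0208), pericentral hepatocyte genes at -0.19 (17 of 21, 0.0130) and hepatocyte secreted proteins at -0.09 (28 of 29, 0.0154). In the skeletal muscle list 1 gene passed over all genes, Mb, which is also a heart gene, and 2 were lower adjusted over the list alone, while Mylpf was at 5.77 and 2.70 FPKM in SunTag against 4.09 and 1.77 in WT (adjusted p = 1). No gene of the other 4 lower lists passed either way. Endothelial markers had a median of -0.03 (camera adjusted p = 0.858, and 0.991 with an estimated correlation).

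SunTag replicate 1 stood apart from the other 3 libraries in several markers of these lists. Cd74, the invariant chain of MHC class II on antigen-presenting cells, was at 214 FPKM in SunTag replicate 1 and 65.9 in replicate 2, against 77.6 ± 17.5 (SD, n = 2) in WT, and Cd52, a lymphocyte surface antigen, at 41.8 and 14.6 against 13.2 ± 1.15. C1qa, a complement component made by macrophages, was at 133 and 72.7 FPKM against 80.8 ± 14.8, and the stellate cell lectin Colec11 at 48.1 and 26.2 against 24.3 ± 3.55. The pericentral genes Glul, glutamine synthetase, and Cyp2e1 were at 156 and 356 FPKM against 385 ± 30.6, and at 1317 and 2501 against 2568 ± 175. Cox7c of the respiratory chain was at 1225 and 728 FPKM against 640 ± 53.5, and Pcna, a replication factor, at 28.5 and 19.1 against 18.5 and 15.6. For other members it did not stand apart in this way: both SunTag libraries lay above both WT libraries for Zfp36, an immediate early gene, at 53.3 and 44.4 FPKM against 33.3 ± 8.32, and below them for Cyp27a1, at 167 and 202 against 250 ± 11.1, while Des was at 2.44 and 1.62 against 2.35 ± 0.178, lowest in SunTag replicate 2. None of these genes passed (adjusted p = 1 for each).

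Without SunTag replicate 1, 8 lists passed, 3 of them among the 13 (erythroid, skeletal muscle and interferon). The macrophage, cell cycle, pericentral and bile acid medians then changed sign, to -0.01 (adjusted p = 0.782), -0.03 (0.566), 0.16 (0.0586) and 0.01 (0.773), and the direction of the test turned for the lymphocyte list (median 0.02, adjusted p = 0.436) and the endothelial list (0.08, 0.172). In the same fit the stellate (median 0.13, adjusted p = 0.0586), respiratory chain (0.06, 0.0889), immediate early (0.24, 0.110), secreted protein (-0.07, 0.110) and female-biased (-0.19, 0.566) lists did not pass. Without WT replicate 1 the macrophage (median 0.17, adjusted p = 0.392), immediate early (0.07, 0.491), interferon (0.00640, 0.967), bile acid (-0.16, 0.319) and female-biased (-0.08, 0.617) lists did not pass. Without WT replicate 2 the cell cycle (0.22, 0.0558), pericentral (-0.13, 0.166) and secreted protein (-0.00589, 0.808) lists did not pass, and without SunTag replicate 2 the interferon (0.10, 0.947), skeletal muscle (-0.33, 0.0958) and secreted protein (-0.14, 0.0909) lists did not. The female-biased list also did not pass without Myod1_control replicate 1 (0.120) or replicate 2 (0.119). With no filter on low values 8 of the 13 lists passed, without the lymphocyte (0.0793), interferon (0.105), secreted protein (0.0781), bile acid (0.0767) and female-biased (0.0767) lists. The female-biased list also did not pass with a pseudocount of 0.1 (0.0506), a filter on the mean FPKM (0.0528), quantile normalization (0.0553) or a fit of these 4 libraries alone (0.109), nor the interferon list with a pseudocount of 0.1 (0.0658) or median-ratio scaling (0.0556), the lymphocyte list with the mean filter (0.0573) or the secreted proteins in the fit of 4 libraries (0.0576).

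**Figure D3:**
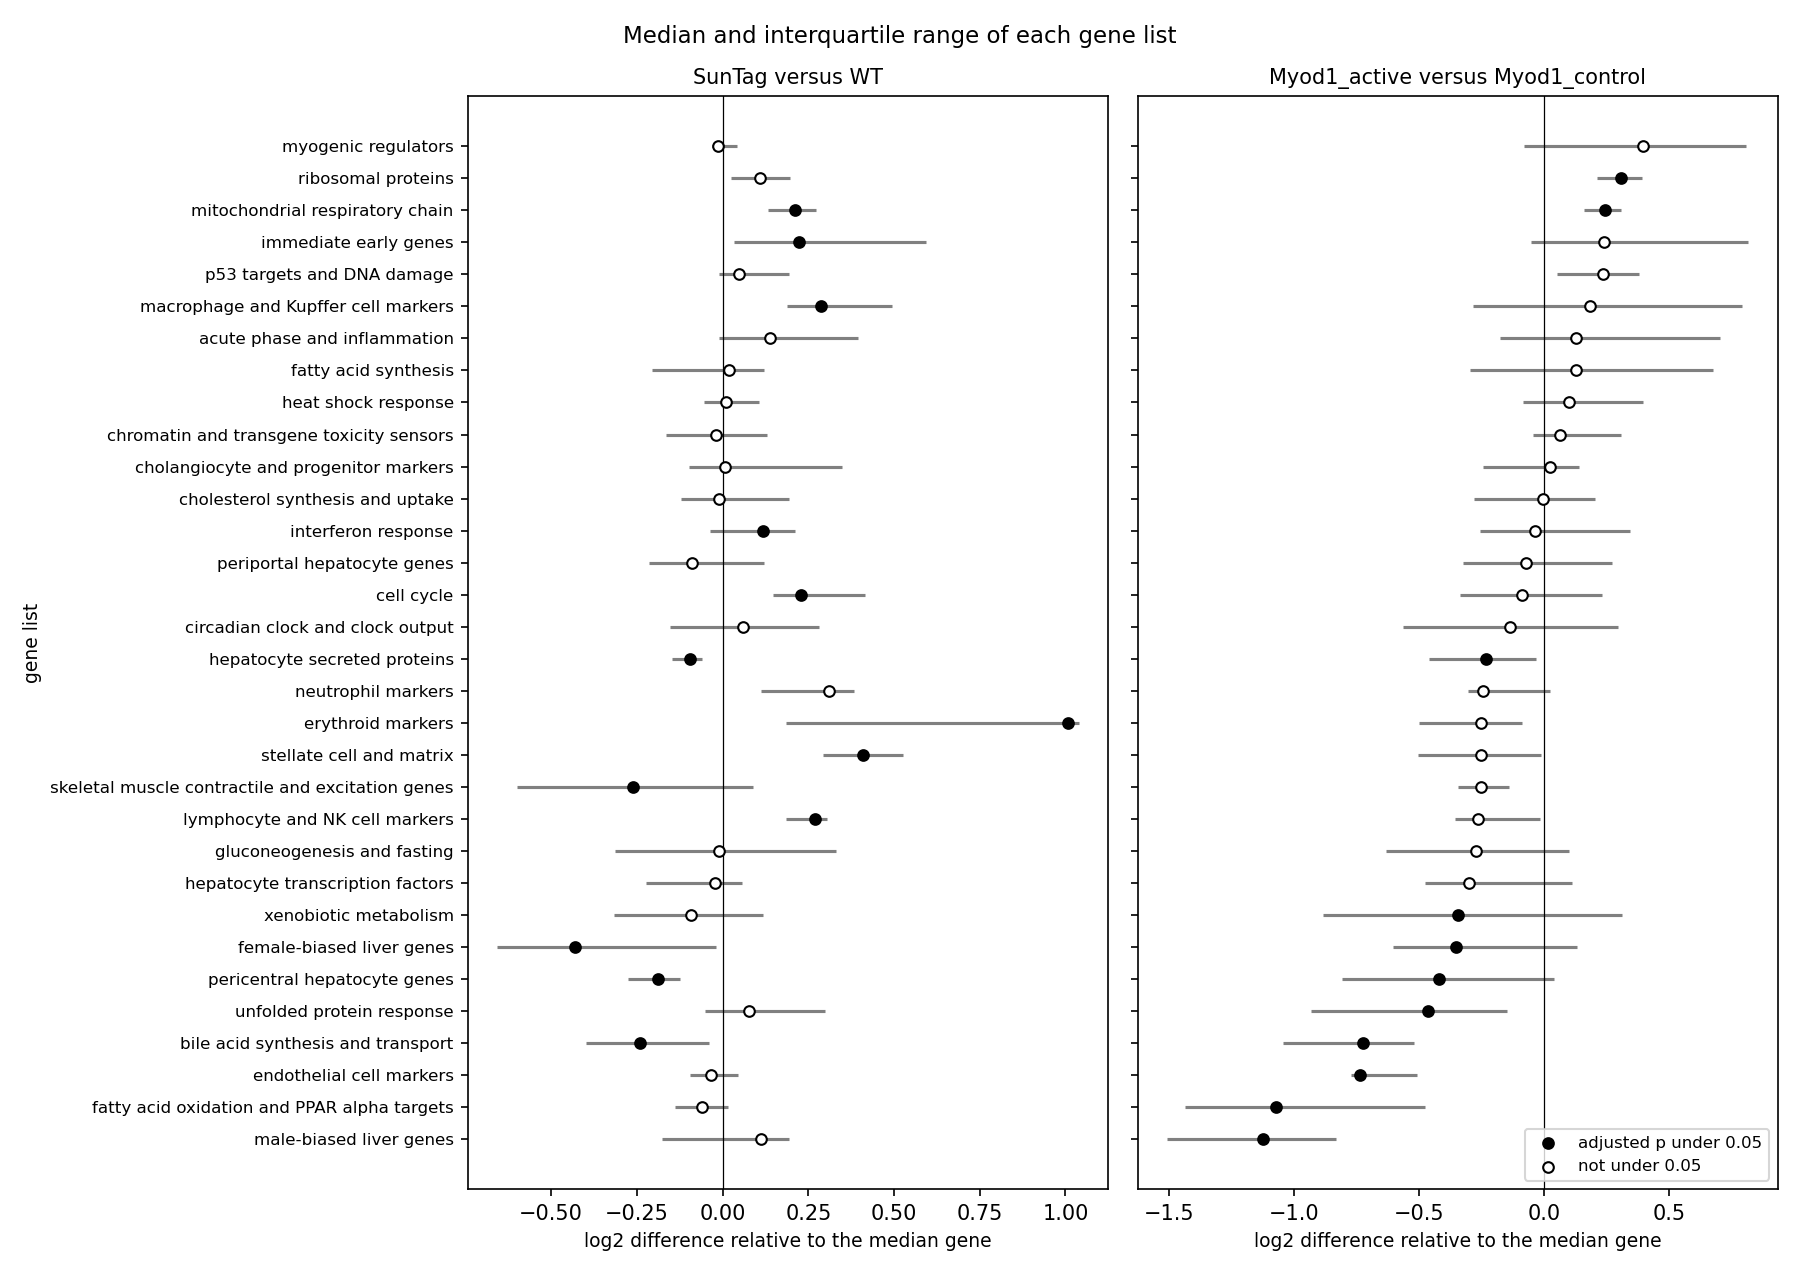
Median (points) and interquartile range (lines) of the log2 difference of each of 32 gene lists relative to the median gene, for SunTag against WT (left) and Myod1_active against Myod1_control (right). Filled points had a camera adjusted p under 0.05, 13 lists on the left and 11 on the right, with the erythroid list highest on the left (1.01) and the male-biased list lowest on the right (-1.13).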

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

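The minimum span of 300 bp, alone and with median-ratio scaling, was chosen after seeing the data. Causes were not tested unless said. For SunTag against WT the count of 20 genes was 5 with that span, 5 with scaling added, and 27 to 78 with 1 library left out. Its 13 lists became 8 with no filter, 0 with an estimated correlation, and 8 to 15 with 1 library left out. For Myod1_active against Myod1_control the 40 genes became 23 with a pseudocount of 0.1, 253 with no filter, 20 with the span, 9 with scaling added, 0 in the fit of those 3 libraries, which leaves 1 residual degree of freedom, and 48 to 122 with 1 library left out. Its 11 lists became 7 with quantile normalization and 0 with an estimated correlation. The Myod1 difference of 2.18 was 5.18 with a pseudocount of 0.1, 2.01 with quantile normalization, and 2.18 with the mean filter, which tests fewer genes, and in the fit of 3 libraries; none of these passed. For Myod1_control against SunTag the 3832 genes became 48 in the fit of those 4 libraries, 1975 with a 2-fold threshold, and 48 to 4036 with 1 library left out, and the 18 lists 0 with an estimated correlation. The replicate numbers, 2 per group, were not taken as pairs: differences between same-numbered libraries correlated across genes at 0.10 for WT and SunTag, 0.06 for WT and Myod1_control and 0.06 for SunTag and Myod1_control. With the replicate block the 3 counts of genes were 15, 23 and 2928, those of lists 12, 11 and 18, and the Myod1 difference was 2.18 and did not pass (adjusted p = 0.222). Of the named genes that passed without it, Tnnt2 (0.0633), Myl3 (0.0970) and Myh6 (0.125) did not pass with it for SunTag against WT, nor Cryab (0.129) and Cpm (0.136) for Myod1_active. Its 11 lists for Myod1_active shared 8 with those without it, and pericentral hepatocyte genes (median -0.0441, adjusted p = 0.0559), xenobiotic metabolism (0.102) and ribosomal proteins (0.129) did not pass, nor did the interferon response for SunTag against WT (0.0711). For SunTag against WT, leaving out 1 library gave medians of -0.0105 to 0.69 for macrophage and Kupffer cell markers, 0.0240 to 0.59 for lymphocyte and NK cell markers, -0.0317 to 0.61 for cell cycle, -0.59 to 0.16 for pericentral hepatocyte genes, -0.31 to 0.0115 for bile acid synthesis and transport and -0.11 to 0.0797 for endothelial cell markers, and differences of -0.21 to 1.46 for Cd74, -0.14 to 0.71 for C1qa and -0.35 to 0.0268 for Des. Des changed sign without SunTag replicate 2, and the others changed the sign or the direction of the test without SunTag replicate 1. For Myod1_active the median turned to 0.19 for secreted proteins with quantile normalization. With no filter that of myogenic regulators was -0.0683, which only reflects the shift taken off every gene in that fit. Depth was unknown, so what it limits could not be stated.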

Other observations

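Of the tests in this part, that of skeletal muscle RNA was set before its result was seen, and the other 5, on heart muscle, non-hepatocyte cells, blood, scaling and variation between livers, were chosen after it.

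The libraries of the Myod1 experiment differed widely from those of the first experiment, and the comparison of Myod1_control with SunTag, both from SunTag-dCas9 mice, measured that distance. Xist, the RNA that silences an X chromosome in female cells and a gene chosen after its values were seen, was at 56.9 to 82.2 FPKM in the WT and SunTag libraries and at 0.00420 to 0.324 in the 3 libraries of the Myod1 experiment, while the Y-linked Eif2s3y was at 0 to 0.531 and at 30.3 to 37.3. Male-biased liver genes lay higher in Myod1_control than in SunTag, at a median log2 difference of 2.30 relative to the median gene with 12 of 19 passing, all higher (13 adjusted over the list alone, camera adjusted p = 2.64e-11, and 0.573 with an estimated correlation). Among them Elovl3, a fatty acid elongase, rose from 0.156 ± 0.0345 to 333 ± 66.0 FPKM (SD, n = 2 each; adjusted p = 0.000673) and Cyp4a12a, uncertain because of its near-identical copy Cyp4a12b, from 0.199 ± 0.125 to 142 ± 33.8 (0.00112). Female-biased genes lay lower, at -3.44 with 15 of 22 lower and 1 higher (16 and 2 adjusted over the list alone, camera adjusted p = 9.30e-06, and 0.573 with an estimated correlation). One of them, the cytochrome P450 Cyp2b9, fell from 174 ± 90.3 to 0.372 ± 0.412 FPKM (0.00807). Genes of fatty acid oxidation and PPAR alpha targets lay higher, at 0.9999 with 14 of 28 passing (15 adjusted over the list alone, camera adjusted p = 1.40e-07, and 0.573 with an estimated correlation), and ribosomal proteins lower, at -0.99 with 21 of 35 passing (33 adjusted over the list alone, camera adjusted p = 1.40e-07, and 0.598 with an estimated correlation). The zinc-binding metallothionein Mt1 fell from 975 ± 26.6 to 9.22 ± 3.81 FPKM (0.00750). The test called 1149 genes higher and 2683 lower. With median-ratio scaling it called 1589 higher and 2015 lower, and with quantile normalization 1757 higher and 1764 lower. The count of 3832 fell to 48 without WT replicate 1 (20 higher and 28 lower), 48 without WT replicate 2 (20 and 28), 135 without Myod1_control replicate 1 (103 and 32), 127 without Myod1_control replicate 2 (92 and 35) and 939 without SunTag replicate 1 (190 and 749), and was 48 in a fit of these 4 libraries alone (21 and 27). Cyp2b9 did not pass without WT replicate 1 (0.0698), WT replicate 2 (0.0696), Myod1_control replicate 1 (0.0618) or replicate 2 (0.0544). Of 32 lists 18 passed camera, 14 passed fry, and 0 passed camera with an estimated correlation, where 1 had an unadjusted p under 0.05. The estimated correlation called 0 of 10 shifted lists in the simulation of this comparison, so it decides little here. The groups did not overlap for 66.6% of genes, where chance gives 33.3%, and an exact permutation test of 2 against 2 cannot give a p under 0.333. Sex split these libraries as the experiments did, and batch or treatment, which were not given in the sources used here, cannot be told apart from either.

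Both WT libraries held several heart muscle transcripts that the other 5 libraries lacked or held at low levels. RNA from heart tissue in the WT samples is a candidate explanation: of 42 listed heart muscle genes above 0 in the WT and SunTag libraries, 88.1% were higher in both WT libraries than in both SunTag libraries, where chance gives 16.7%, and 32 of the 37 that were not called (86.5%) did the same. Fast skeletal muscle as the source was argued against, since fast skeletal muscle genes summed to 8.70% and 4.66% of the 7 core heart genes in the WT libraries, under the 10% set beforehand. Their sums were 4.39 and 2.50 FPKM in WT against 6.51 and 3.15 in SunTag. Other skeletal muscle was not covered by that list, so the test does not speak to it. The 7 core genes had ratios of WT replicate 1 to WT replicate 2 between 0.708 and 1.21. Not all of the list went this way: 2 genes were lower in both WT libraries than in both SunTag libraries. Csrp3 was at 26.6 and 20.2 FPKM in WT and still at 13.1 to 17.5 in the other 5 libraries. Of the list, 5 genes also reached an FPKM of 1 in a library other than WT, the core genes were low even in WT, up to 15.0 FPKM for Myl2 in WT replicate 1, and a difference in expression caused by the genotype stays open, as untested.

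Markers of blood and of cells other than hepatocytes were low in the 3 libraries of the Myod1 experiment. The globin genes summed to 2327 to 6367 FPKM in the WT and SunTag libraries and to 1.71 to 5.67 in the others, and Hba-a1 fell from 1580 ± 491 in SunTag to 1.02 ± 0.325 in Myod1_control (SD, n = 2 each; adjusted p = 0.000949), while Alas2, an erythroid enzyme also chosen after its values were seen, rose from 17.8 ± 5.58 to 41.2 ± 4.15 (0.0299; 0.0870 without WT replicate 1, 0.0871 without WT replicate 2, 0.128 without Myod1_control replicate 1 and 0.110 without replicate 2). Removal of blood alone was argued against as the source of the whole pattern, because the endothelial list also lay lower, with a median of -1.28 (interquartile range -1.65 to -0.97). For the globin genes, at a median of -8.99, removal of blood stays open. Fewer cells other than hepatocytes might account for the rest, but the 4 lists gave -1.28 for endothelial, -1.58 for macrophage, -1.16 for lymphocyte and -0.87 for stellate markers, and the highest, -0.87, lay between the bounds of -1 and -0.5 set for that test. That explanation, sex and any difference in batch or treatment cannot be told apart, since sex and experiment split the libraries the same way.

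Male-biased genes and PPAR alpha targets lay lower in the Myod1_active library than in its controls. For the PPAR alpha list the WT and SunTag libraries lay below the controls too, at mean log2 values of 5.19 to 5.57 against 6.13 and 6.60. That gap runs between experiments and sexes, which cannot be told apart. Median-ratio scaling could not test a scaling difference, since both list medians were already relative to the median gene. After it the male-biased list had a median of -1.17 (interquartile range -1.56 to -0.88), and the PPAR alpha list -1.10. Variation between livers unrelated to Myod1 could contribute: the 2 controls differed from each other by 0.50 for the male-biased list, against -1.13 for the activated library, and by -0.43 for the PPAR alpha list, against -1.07. With 2 controls and 1 activated library this cannot be told apart from an effect of Myod1 activation, which stays open as a hypothesis without a replicate.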
